A study of Mus musculus with 9 samples.

How the data were processed

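Total RNA of 9 samples was measured on Illumina mouse whole-genome BeadChips, with 3 arrays for each of 3 cell populations sorted by flow cytometry from the mammary gland (Lgr5+ basal, Lgr5- basal and luminal). Per the labels, RNA was extracted with the RNeasy micro kit, up to 125 ng per sample was amplified and labelled with biotin using the Ambion MessageAmp kit, and each sample carries the number of a pool. The submitters' processing notes name GenomeStudio and limma, and their versions are not given in the sources used here. Sort markers, gates and the number of mice per pool are not given in the sources used here either, so p-values measure the spread between pools.

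The deposited raw table held an intensity per probe and array, on a linear scale, neither corrected for background nor normalized. Its detection columns, per the file headers a detection p-value, held a fraction that rose with the signal on every array, so 1 minus that fraction was used as the detection p. Another deposited column held a flag for probes that the authors set aside, and the rule behind it is not given in the sources used here. The second deposited table held log2 values from the authors with nearly identical distributions on all 9 arrays. Every value column belonged to a sample.

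Raw intensities of 45281 probes were corrected for background with the normexp model of limma, with the negative control signal inferred from the detection p and an offset of 16, then quantile normalized and put on the log2 scale. The result differed from the authors' log2 values by at most 0.028 on any array. Probes with a detection p under 0.01 on at least 3 of the 9 arrays were kept, which left 17712 probes. Of the authors' probes, 26391 were set aside and 18890 kept, and all 18890 had a detection p under 0.05 on at least 3 arrays, as did 1595 of those set aside. Probe names were matched to mouse RefSeq symbols (27400 probes) or synonyms (8300 probes), and 9581 probes kept the name in the table. Of the tested gene names, 1760 matched no RefSeq symbol or synonym. The probe with the highest mean over all 9 arrays stood for each gene, which gave 12148 genes, of which 3920 had more than 1 tested probe and 901 rested on a probe that the authors set aside. No coordinates are given, since the files name no genome build.

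Mean raw intensity per array ran from 428.1 to 654.4, and 33.65% to 38.48% of the probes were detected. The number of arrays, 3 per group, limits the precision.

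The 3 groups were compared in pairs with linear models and moderated statistics (limma 3.58.1 in R 4.3.3) fitted to all 9 arrays, with 6 residual and 4.36 prior degrees of freedom, two-sided, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. Values are normalized log2 intensities as mean ± SD (n = 3 arrays), and differences are log2 differences between group means. Where a probe was detected on none of the arrays of the lower group, values of that group were raised to the lowest level at which any probe of the same array was called detected, and the difference is written as at least N-fold. These bounds hold for background-corrected values, and without the correction the differences of genes near background were smaller. A gene was called separated when all 3 values of one group lay above all 3 of the other, which chance gives for 10% of genes.

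Before the data were examined, 25 gene lists with 523 distinct genes were fixed: basal keratin and adhesion, smooth muscle contractile, luminal pan-epithelial, luminal hormone-sensing, luminal progenitor and milk, Wnt target and feedback, Wnt ligand and receptor, intestinal Lgr5 stem cell signature, reported mammary stem cell and basal regulator, Notch pathway, TGF-beta and BMP pathway, extracellular matrix and basement membrane, cell cycle, immediate-early and dissociation stress, interferon response, Hox genes, and markers of fibroblasts, endothelium, pericytes, haematopoietic cells, erythroid cells, adipocytes, Schwann cells, epidermal differentiation and skeletal muscle. Of these genes, 354 were tested. The 23 lists with at least 5 tested members were compared with all other genes by camera of limma with a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance, were run beside it.

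Genes are named by a rule fixed at the same time: in each comparison the 10 genes with the largest change in each direction that passed the threshold and were separated, leaving out clone and predicted-gene names; the 4 tested members of each list with the smallest p; and 22 landmark genes, among them Lgr5, Krt5, Krt14, Krt8, Krt18, Axin2, Tspan8 and Procr. Some are left out for space. A gene named outside this rule is said to have been chosen after its values were seen.

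The pool number was checked as a pairing of the samples: after group means were removed, the residuals of Lgr5+ and Lgr5- basal arrays of the same pool correlated across genes with r of 0.35, 0.23 and 0.45 in pools 1, 2 and 3, against at most 0.03 between pools. For Lgr5- basal and luminal arrays, r was 0.30, 0.11 and 0.36, against at most 0.04 between pools, and for Lgr5+ basal and luminal arrays 0.11, 0.09 and 0.14, against at most 0.01. Genes are not independent replicates. The pools were therefore fitted as a replicate block, which called 160, 6475 and 5971 genes in the 3 comparisons (Lgr5+ basal against Lgr5- basal, Lgr5+ basal against luminal, Lgr5- basal against luminal) where the fit without a block called 128, 5961 and 5430.

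The procedure was tested on simulated data for the comparison of Lgr5+ with Lgr5- basal cells. The spread was that of the fit to all arrays, luminal ones included, and not that of the basal arrays alone. Signal shared by arrays of a pool was not simulated, so the rates below do not cover it. Among 12148 genes, 100 were changed 2-fold and 100 were changed 4-fold. Over 10 runs the procedure recovered 56.3% and 93.8% of them, with 4.7% of the calls false and 0 calls of the wrong sign. A list of 20 genes shifted by 0.5 on the log2 scale was called in 10 of 10 runs, and an unshifted list in 1 of 10. These calls were camera with the preset correlation at an unadjusted p under 0.05. Lists whose genes move together were not simulated, so the runs do not test list calls for such genes.

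Alternatives were quantile normalization without background correction, cyclic loess, median centring, the authors' log2 values, looser, stricter and no detection filters, all probes or the mean of a gene's probes, pool as a replicate block or a random block (statmod 1.5.0), BeadChip as a block, each BeadChip alone, the 6 arrays of a comparison alone, array weights, a variance prior with trend and robust estimation, a test against a 1.5-fold change (treat), and leaving out each array and each pool. Keeping the probes that the authors' flag keeps was added after the data had been seen.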

Results

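Expression was profiled in mammary epithelial cells of 10-week-old virgin C57BL/6 mice that carry Lgr5-GFP-IRES-CreERT2, an allele that reports Lgr5 expression through GFP. Lgr5 is a receptor for R-spondins, ligands that strengthen Wnt signalling, and marks stem cells in the intestine. The groups were Lgr5+ basal cells, Lgr5- basal cells (both from the outer, myoepithelial layer of the gland) and luminal cells (from the layer that lines the ducts), with 3 arrays each. Pools 1 and 2 were hybridized on one BeadChip, named BeadChip 1 here, and pool 3 on another, BeadChip 2, each with all 3 groups. Between 15235 and 17423 of 45281 probes were detected per array, and 12148 genes were tested. Across genes, arrays correlated with r of 0.967 to 0.984 within the Lgr5+ basal group, 0.983 to 0.987 within the Lgr5- basal group and 0.967 to 0.982 within the luminal group. Lgr5+ and Lgr5- basal arrays correlated with r of 0.959 to 0.989, and basal with luminal arrays with 0.784 to 0.83.

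Comparing Lgr5+ with Lgr5- basal cells asks what sets Lgr5-expressing cells apart within the basal layer. Lgr5 itself was higher in the Lgr5+ sort, at 10.09 ± 0.49 (SD, n = 3) against 8.44 ± 0.44, a log2 difference of 1.65 (SE 0.285, limma adjusted p = 0.0225). Tspan8, a tetraspanin of the cell membrane, rose most, from 8.51 ± 0.35 in Lgr5- to 11.79 ± 0.23 in Lgr5+ cells, 9.66-fold (log2 difference 3.27, adjusted p = 0.000354). Sfrp1, a secreted Wnt antagonist, rose from 8.84 ± 0.30 to 11.69 ± 0.30 (log2 difference 2.85, adjusted p = 0.000354). Dcn, the collagen-binding proteoglycan decorin, fell from 13.24 ± 0.06 to 11.78 ± 0.11 (log2 difference -1.47, adjusted p = 0.00305). Each of these genes was separated, which fixes its sign in all 3 pools. For Lgr5 the differences were 1.54, 1.69 and 1.71 in pools 1, 2 and 3. Lgr5 was detected on the Lgr5- basal arrays and on none of the luminal arrays. Lgr4 and Procr were not detected on enough arrays to be tested.

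**Figure D1:**
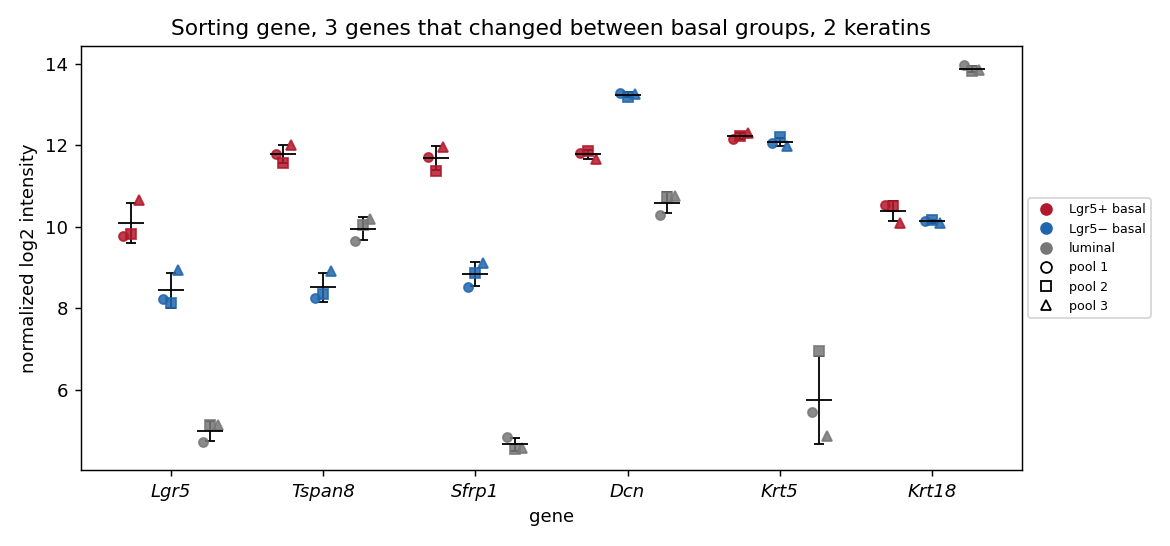
Normalized log2 intensity (vertical axis) of 6 genes on each of the 9 arrays, coloured by group and shaped by pool, with the mean and SD of 3 arrays as lines. Lgr5, Tspan8 and Sfrp1 lie higher and Dcn lower in Lgr5+ than in Lgr5- basal arrays, while the log2 difference between them is 0.13 for Krt5 and 0.25 for Krt18.

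In all, 128 of the 12148 genes changed between the basal groups (limma), 61 higher and 67 lower in Lgr5+ cells, and 108 of them by at least 2-fold. All 128 were separated, and 2583 genes (21.3%) were separated in all, against 10% by chance. Beyond Tspan8 and Sfrp1, the largest rise was of Cfd, the complement protease adipsin (at least 5.46-fold, adjusted p = 0.022). Next came Cntn2, a neuronal adhesion protein (2.16, adjusted p = 0.0305), Ptprd, a receptor tyrosine phosphatase (2.07, adjusted p = 0.0081), and Frmpd4 (at least 3.1-fold, adjusted p = 0.0169). Lrrtm1 rose by 1.98 (adjusted p = 0.0214), Gli2, a transcription factor of the Hedgehog pathway, at least 2.84-fold (adjusted p = 0.00223), Myo5b, a motor of recycling endosomes, by 1.76 (adjusted p = 0.00332), and Pygl, a glycogen phosphorylase, by 1.76 (adjusted p = 0.00506). Among the genes lower in Lgr5+ cells, Lamp5, detected on 1 of 3 Lgr5+ arrays, had a log2 difference of -2.91 (adjusted p = 0.0271), Esm1, a secreted proteoglycan, of -2.56 (adjusted p = 0.0258), Col9a1, a collagen chain, of -2.52 (adjusted p = 0.00236), and Tex36 of -2.49 (adjusted p = 0.000952). Spock3 was at least 3.39-fold lower (adjusted p = 0.00236), and Aldh1a1, an enzyme that makes retinoic acid, and Uts2b, a urotensin peptide, both had a log2 difference of -2.24 (adjusted p = 0.00551 and 0.00107). Lbhd2 (-2.17, adjusted p = 0.00626), Ugt1a6a (-2.09, adjusted p = 0.0424) and Lrrn1 (-1.88, adjusted p = 0.00649) completed the largest falls. Lrrn1 was detected on 1 of 3 Lgr5+ arrays, and Aldh1a1, Col9a1, Esm1 and Ugt1a6a on 2 of 3. Ptprd was detected on 1 of 3 Lgr5- arrays. The lower values of these genes lay near background, so the sizes of their differences are uncertain. Of these 20 genes, 13 passed without any single array. The other 7 (Cfd, Cntn2, Frmpd4, Lrrtm1, Lamp5, Esm1 and Ugt1a6a) all lost the call without Lgr5- basal replicate 1 or 2, and some of them without Lgr5- basal replicate 3, Lgr5+ basal replicate 1 or 2 or a luminal array, with adjusted p up to 0.151. Without background correction Cfd differed by 1.24 (adjusted p = 0.0741), Cntn2 by 1.27 (0.0611), Frmpd4 by 0.69 (0.0913), Lamp5 by -1.35 (0.0611) and Ugt1a6a by -0.88 (0.0655), and none of these passed. With pool as a replicate block Esm1 (0.0511) and Ugt1a6a (0.0741) did not pass.

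**Figure D2:**
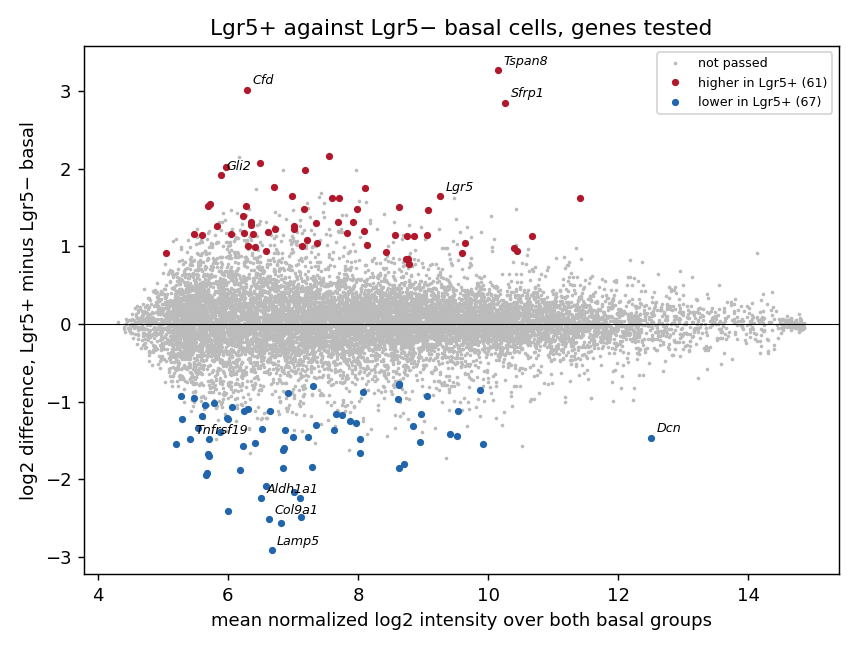
Log2 difference between Lgr5+ and Lgr5- basal means (vertical axis) against the mean normalized log2 intensity of each of the 12148 genes (horizontal axis), with the 61 genes that rose and the 67 that fell in colour. Tspan8 lies highest, at 3.27.

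None of the 18 tested basal keratin and adhesion genes and none of the 17 smooth muscle contractile genes passed in limma, over all genes or adjusted over the list alone, and 2 members of each list had an unadjusted p under 0.05. Krt5 differed by 0.13 (adjusted p = 0.938), Krt14 by -0.04 (adjusted p = 0.991), the smooth muscle actin Acta2 by 0.04 (adjusted p = 0.99) and Trp63, a transcription factor of basal epithelium, by -0.06 (adjusted p = 0.976). The probes of Krt14 and Acta2 lay at 75.2% to 91.5% and 71.1% to 80.5% of the array maximum in basal cells, where a difference can be compressed. The other 4 tested Acta2 probes differed by -0.61, -0.07, -0.70 and -0.50, and none passed (lowest adjusted p over probes 0.597). The keratin list had a median of -0.01 (adjusted p = 0.75). The smooth muscle list had a median of -0.31 with 4 of 17 genes positive (adjusted p = 0.311), and medians of -0.06, -0.25 and -0.14 in pools 1, 2 and 3. Luminal keratins Krt8 (0.11, adjusted p = 0.809) and Krt18 (0.25, adjusted p = 0.555) did not pass either. The luminal pan-epithelial list (median 0.12, adjusted p = 0.696), the hormone-sensing list (-0.10, adjusted p = 0.988) and the progenitor and milk list (-0.02, adjusted p = 0.696) had 0 of 17, 0 of 16 and 0 of 18 members past the threshold. In these lists 1, 4 and 2 members had an unadjusted p under 0.05, and 2 hormone-sensing genes were higher when adjusted over the list alone. Tbx3, a T-box factor of the hormone-sensing list, passed with pool as a replicate block (0.98, adjusted p = 0.0355).

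Of 13 tested Wnt target and feedback genes, 0 rose, 1 fell and 12 did not pass, against 1 higher and 3 lower adjusted over the list alone. Tnfrsf19, a Wnt-induced receptor of the TNF family, fell at least 1.65-fold (adjusted p = 0.00319), while Axin2, a widely used Wnt target, differed by 0.00 (adjusted p = 0.997) and Nkd2 by -0.97 (adjusted p = 0.055). The list had a median of -0.24 and did not pass (camera adjusted p = 0.0597), though it did without Lgr5+ basal replicate 2 (0.014), Lgr5- basal replicate 2 (0.0455), Lgr5- basal replicate 3 (0.0425) or luminal replicate 2 (0.0409). Camera with an estimated correlation gave adjusted p = 0.643 with all arrays and 0.521 without Lgr5+ basal replicate 2. Of 24 Wnt ligands, receptors and antagonists, Sfrp1 rose, Ror2, a Wnt5a receptor, fell at least 2.17-fold (adjusted p = 0.00236) and 22 did not pass, with 3 higher and 2 lower adjusted over the list alone (list adjusted p = 0.988). Sfrp2 differed by 1.41 (adjusted p = 0.0543), Wnt6 by -1.31 (adjusted p = 0.0992) and Lgr6 by -0.20 (adjusted p = 0.632). With pool as a replicate block Sfrp2 (adjusted p = 0.0283) and Nkd2 (0.0193) passed, and Wnt6 (0.0615) and Lgr6 (0.503) did not. Within pools 1, 2 and 3, Sfrp2 differed by 1.34, 1.45 and 1.43, Nkd2 by -1.06, -0.96 and -0.88 and Wnt6 by -1.54, -1.17 and -1.22. In the intestinal Lgr5 stem cell signature, of 13 genes only Tnfrsf19 passed (1 higher and 1 lower adjusted over the list alone, list adjusted p = 0.988). Among 20 reported mammary stem cell and basal regulators, Tspan8 rose, Tbx2, a T-box transcription factor, fell by 1.53 (adjusted p = 0.0169) and 18 did not pass, with the same counts of 1 and 1 adjusted over the list alone (list adjusted p = 0.988). The fall of Tbx2 did not pass without Lgr5+ basal replicate 2 (0.0624), Lgr5- basal replicate 2 (0.084) or Lgr5- basal replicate 3 (0.0593).

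The cell cycle list lay lower in Lgr5+ cells as a set, with a median of -0.55, 2 of 24 genes positive and a camera adjusted p of 8.86e-06. The genes of this list moved together (correlation 0.449), and the list had adjusted p = 0.997 with an estimated correlation and fry adjusted p = 0.48. No member passed in limma, over all genes or adjusted over the list alone, and 7 had an unadjusted p under 0.05. Mki67, a marker of cycling cells, differed by -0.37 (adjusted p = 0.73) and Ccnb1, a mitotic cyclin, by -0.79 (adjusted p = 0.276). Medians were -0.91, -0.59 and -0.05 in pools 1, 2 and 3. No other list passed. The Notch pathway had a median of -0.03 (adjusted p = 0.996), the TGF-beta and BMP pathway of 0.20 (adjusted p = 0.879) and the extracellular matrix list of 0.11 (adjusted p = 0.988). Of their members 0 of 14, 0 of 21 and 0 of 27 passed in limma, with 1, 7 and 8 at an unadjusted p under 0.05. The smallest p among them belonged to genes such as the receptor Notch1 (0.80, adjusted p = 0.0759), Fst (-0.89, adjusted p = 0.123) and the laminin chain Lama1 (-1.58, adjusted p = 0.105). With pool as a replicate block these had adjusted p = 0.0783, 0.102 and 0.103, and Lama1 differed by -1.48, -1.55 and -1.71 within pools 1, 2 and 3. Adjusted over the list alone, 1 Notch gene was higher, 2 TGF-beta and BMP genes were higher and 1 lower, and 2 matrix genes were higher and 2 lower. Immediate-early and dissociation stress genes (median 0.17, adjusted p = 0.268), interferon response genes (0.07, adjusted p = 0.996) and Hox genes (0.22, adjusted p = 0.664) did not pass. Of their members 0 of 24, 0 of 15 and 0 of 8 passed in limma, with 3, 2 and 1 at an unadjusted p under 0.05 and 0 adjusted over the list alone. The stress list passed without Lgr5+ basal replicate 2 (adjusted p = 0.0407) or luminal replicate 2 (0.0409), and the smooth muscle list without luminal replicate 2 (0.0409). With all arrays the Wnt target, stress and smooth muscle lists had adjusted p = 0.643, 0.997 and 0.997 with an estimated correlation.

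The fixed marker lists of other cell types gave 4 calls between the basal groups. Esm1, among the largest falls, stood in no fixed list, so the endothelial counts here do not cover it. Of 16 fibroblast genes, Dcn fell and 15 did not pass (1 higher and 1 lower adjusted over the list alone, median 0.08, adjusted p = 0.988). With pool as a replicate block Mfap5, a microfibril protein of the fibroblast list, passed (1.27, adjusted p = 0.0331). Of 9 pericyte genes, Mcam, an adhesion molecule, rose by 1.04 (adjusted p = 0.0411; 1 higher adjusted over the list alone, list median 0.04, adjusted p = 0.75). Of 10 haematopoietic genes, Cd3e, a T cell receptor chain, fell by 0.88 (adjusted p = 0.0306; 1 lower adjusted over the list alone, list median 0.25, adjusted p = 0.988). Of 6 adipocyte genes, Cfd rose (1 higher and 1 lower adjusted over the list alone, median 0.02, adjusted p = 0.988). The calls of Mcam and Cd3e were lost without Lgr5+ basal replicate 1 or 2, any Lgr5- basal replicate or luminal replicate 1, with adjusted p up to 0.176 and 0.154, and that of Mcam with pool as a replicate block (0.0569). None of 14 endothelial, 7 Schwann cell and 10 epidermal differentiation genes passed, with 0, 3 and 0 at an unadjusted p under 0.05 and 0 adjusted over the list alone (list adjusted p = 0.988, 0.456 and 0.9). The endothelial genes stood apart on 1 array: their median level was 9.26 in Lgr5+ basal replicate 2, against 7.90 and 6.90 in the other Lgr5+ basal arrays and 7.73 to 8.03 in the Lgr5- basal arrays. Without that array their median difference turned from 0.05 to -0.60 (adjusted p = 0.00236, but adjusted p = 0.835 with an estimated correlation of 0.591), the count of changed genes was 62, and 57 of these were among the 128. The 2 erythroid genes (median 0.89) and 4 skeletal muscle genes (median 0.26, 2 higher and 1 lower adjusted over the list alone) were too few for a list test, with 0 past the limma threshold and 0 and 3 at an unadjusted p under 0.05.

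Median, mean and camera direction differed in sign for 7 lists in this comparison. These were Wnt ligands and receptors (median -0.07, mean 0.11, up), extracellular matrix (0.11, -0.05, down) and the intestinal signature (0.10, -0.03, up). The others were mammary stem cell regulators (-0.07, 0.01, down), Notch (-0.03, 0.01, down), adipocyte (0.02, 0.19, down) and basal keratin and adhesion genes (-0.01, 0.16, up). With BeadChip as a block 191 genes changed, the 128 among them, and within BeadChip 1 alone 331 genes, 100 of them among the 128. All 128 genes were separated, which fixes their sign within each BeadChip, and BeadChip 2 holds 1 array per group, so it gives values with no test. For Lgr5 the difference with BeadChip as a block had an adjusted p of 0.00379, and it was 1.62 within BeadChip 1 (adjusted p = 0.0176) and 1.71 within BeadChip 2. Tspan8 differed by 3.36 within BeadChip 1 (adjusted p = 0.00138) and by 3.10 within BeadChip 2 (block adjusted p = 5.55e-05). Sfrp1 differed by 2.85 within each (adjusted p = 0.00385 within BeadChip 1, block 0.000435) and Dcn by -1.40 and -1.61 (adjusted p = 0.0231 within BeadChip 1, block 0.00382). Tbx2 (-1.53, adjusted p = 0.0518) and Cd3e (-0.78, adjusted p = 0.0845) did not pass within BeadChip 1. The cell cycle list kept its call with BeadChip as a block (median -0.55, adjusted p = 2.97e-06) and within BeadChip 1 (-0.79, adjusted p = 6.92e-10), and its median was -0.05 within BeadChip 2. Both calls use the preset correlation, and with all arrays that list had camera adjusted p = 0.997 with an estimated correlation and fry adjusted p = 0.48. The count depended on single arrays and on the scaling: it was 59 without Lgr5+ basal replicate 1, 604 without Lgr5+ basal replicate 3, 52 without Lgr5- basal replicate 1, 52 without Lgr5- basal replicate 2, and 52 with median centring, where 36.5% were higher against 47.7%. The rise of Lgr5 did not pass without replicate 1 (0.0509) or 2 (0.0554) of the Lgr5+ or replicate 1 (0.116) or 2 (0.104) of the Lgr5- basal arrays, nor with median centring (0.102).

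Comparing Lgr5+ basal with luminal cells asks how the sorted cells differ from the inner layer. Keratin and contractile genes of the basal layer were higher in Lgr5+ cells, all 18 basal keratin and adhesion genes and all 17 smooth muscle contractile genes among them. Krt5 stood at 12.22 ± 0.07 (SD, n = 3) against 5.75 ± 1.08 (log2 difference 6.47, limma adjusted p = 4.41e-07), and Myh11, smooth muscle myosin, at 13.16 ± 0.22 against 6.32 ± 1.49 (6.84, adjusted p = 2.72e-06). All 17 tested luminal pan-epithelial genes were lower, among them Krt18 at 10.38 ± 0.25 against 13.88 ± 0.08 (-3.50, adjusted p = 7.1e-08) and Krt7 (-4.71, adjusted p = 1.77e-07). After background correction Lgr5 was at least 23.6-fold higher than in luminal cells (adjusted p = 1.94e-07), and without the correction its log2 difference was 2.86 (adjusted p = 1.9e-06). Tspan8 was higher than in luminal cells, at 11.79 ± 0.23 against 9.96 ± 0.28 (1.83, adjusted p = 6.1e-05).

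Here 5961 of 12148 genes changed (limma), 3006 higher and 2955 lower in Lgr5+ basal cells, 3516 of them by at least 2-fold and 623 by at least 8-fold, and 54.8% of genes were separated, against 10% by chance. The largest rises included Cxcl14, a chemokine (7.60, adjusted p = 3.4e-08), and Slpi, a secreted protease inhibitor (6.89, adjusted p = 4.41e-07). Cxcl14 and Slpi lay at 77.1% and 79.7% of the array maximum in Lgr5+ cells, where a difference can be compressed. The largest rises also included Igfbp3, which binds insulin-like growth factors (6.86, adjusted p = 5.04e-07), Col17a1, a hemidesmosome collagen (6.61, adjusted p = 3.91e-06), Ecrg4 (6.59, adjusted p = 7.66e-07) and Myl9, a myosin light chain (6.45, adjusted p = 3.18e-06). Col14a1, a fibril-associated collagen, was at least 105-fold higher (adjusted p = 1.32e-08) and Sfrp1 at least 71.5-fold (adjusted p = 1.11e-08). The largest falls were of Cxcl15, a chemokine of secretory epithelia (-6.02, adjusted p = 5.74e-08), Dmbt1, a secreted mucosal scavenger protein (-5.79, adjusted p = 7.43e-06), and Cyp3a57, a cytochrome P450 (-5.66, adjusted p = 4.26e-08). Next came Hp, haptoglobin (-5.53, adjusted p = 1.94e-07), Nup210, a nuclear pore protein (-5.31, adjusted p = 1.07e-06), and ABP1 as named in the files (-5.24, adjusted p = 8.8e-08). They were followed by Ly6d (-5.20, adjusted p = 3.76e-08), Ffar4, a fatty acid receptor (-5.11, adjusted p = 2.96e-07), and Upk3a, an uroplakin, on a probe that the authors set aside (-5.13, adjusted p = 1.26e-05). Msc, the transcription factor musculin, was at least 33.2-fold lower (adjusted p = 1.11e-08). All 20 genes with the largest changes passed without any single array.

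Of 23 tested lists, 13 passed in camera against luminal cells. With an estimated correlation 0 of these calls held, with 10 lists at an unadjusted p under 0.05. Fry called 18 lists, the endothelial list not among them (fry adjusted p = 0.125). Called by fry but not by camera were the intestinal signature (down, 0.0124) and stress genes (up, 0.0217). So were, all up, Hox (0.0101), pericyte (0.000726), haematopoietic (0.00735) and Schwann cell genes (0.031). The counts of members were the same adjusted over the list alone unless given. Basal keratin and adhesion (median 3.21, adjusted p = 5.08e-09), smooth muscle contractile (3.10, adjusted p = 1.64e-09) and extracellular matrix genes (2.59, adjusted p = 4.49e-11) were higher as sets. With members at their lower bound the medians were 3.21, 2.98 and 2.09, and adjusted p = 0.0596, 0.0637 and 0.0637 with an estimated correlation. Of 27 matrix genes 24 rose and 3 did not pass (25 rose adjusted over the list alone), among them Mmp2, a gelatinase (6.43, adjusted p = 1.32e-08), and Hspg2, perlecan (4.63, adjusted p = 2.49e-08). The smooth muscle genes had a median level of 8.04 on luminal replicate 2, against 5.68 and 5.40 on the other luminal arrays. Without luminal replicate 2 the medians of the basal keratin and smooth muscle lists were 3.28 and 3.68, with 5603 genes changed, 5224 of them among the 5961.

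Luminal pan-epithelial (median -3.20, adjusted p = 6.77e-11), hormone-sensing (-3.18, adjusted p = 9.18e-06) and progenitor and milk genes (-2.31, adjusted p = 2.72e-05) were lower as sets, with adjusted p = 0.0596, 0.0596 and 0.149 with an estimated correlation. With members at their bound the medians were -3.20, -3.12 and -1.97. Hormone-sensing genes had 13 members lower, 2 higher and 1 not passed, with Esr1 and Pgr, the oestrogen and progesterone receptors, at -2.76 (adjusted p = 0.000168) and -2.83 (adjusted p = 3.86e-06). Progenitor and milk genes had 14 members lower, 1 higher and 3 not passed, with Elf5, a transcription factor of alveolar fate, at -4.43 (adjusted p = 1.86e-07) and Kit, a receptor tyrosine kinase, at -4.36 (adjusted p = 5.77e-07). Epidermal differentiation genes were lower too (0 higher, 5 lower, 5 not passed, median -1.23, or -0.94 with members at their bound, adjusted p = 0.0186). They had adjusted p = 0.149 with an estimated correlation. Among them was Sprr1a, a protein of cornified envelopes, at least 12.4-fold lower (adjusted p = 5.45e-08). That list did not pass without luminal replicate 2 (adjusted p = 0.0521).

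Wnt target and feedback genes were higher (8 higher, 2 lower, 3 not passed, median 1.19, adjusted p = 0.00804, but adjusted p = 0.0777 with an estimated correlation). Axin2 rose by 2.74 (adjusted p = 4.93e-05) and the secreted Wnt inhibitor Wif1 by 5.52 (adjusted p = 1.08e-07), while Ccnd1, cyclin D1, fell by 2.90 (adjusted p = 6.02e-07). Wnt ligands and receptors (14 higher, 5 lower, 5 not passed, median 1.05, or 0.77 with members at their bound) passed as well (adjusted p = 0.0281, but adjusted p = 0.081 with an estimated correlation). Dkk3 rose by 6.09 (adjusted p = 9.05e-08, on a probe that the authors set aside) and Wnt7b, a Wnt ligand, fell by 4.47 (adjusted p = 6.51e-08). This list did not pass without luminal replicate 2 (adjusted p = 0.062). Mammary stem cell and basal regulators (16 higher, 3 lower, 1 not passed, median 1.47, adjusted p = 0.000214) included Snai2, an epithelial-mesenchymal transcription factor (5.69, adjusted p = 2.92e-07). TGF-beta and BMP genes (12 higher, 1 lower, 8 not passed, median 0.98, or 0.81 with members at their bound, adjusted p = 0.000289) included Fst, follistatin (5.08, adjusted p = 7.55e-08). Their calls had adjusted p = 0.081 and 0.0596 with an estimated correlation. Fibroblast genes (12 higher, 1 lower, 3 not passed, median 1.18, adjusted p = 0.000342) and endothelial genes (8 higher, 0 lower, 6 not passed, median 1.49, adjusted p = 0.0491) passed too. They had adjusted p = 0.081 and 0.705 with an estimated correlation. Fbln1, a matrix glycoprotein, rose by 4.67 (adjusted p = 1.64e-07) and Ptprb, an endothelial phosphatase, by 1.88 (adjusted p = 0.0035). The endothelial call was lost without Lgr5+ basal replicate 2 (median 0.90, adjusted p = 0.157), the array with the high endothelial level, and also without Lgr5- basal replicate 2 (0.05) or luminal replicate 1 (0.0672) or 3 (0.0984).

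The intestinal signature (5 higher, 5 lower, 3 not passed, median -0.20, mean 0.04, camera down, adjusted p = 0.768) did not pass against luminal cells, nor did Notch genes (5 higher, 6 lower, 3 not passed, median -0.06, mean 0.20, camera down, adjusted p = 0.692). Cell cycle (2 higher, 4 lower, 18 not passed, median -0.29, adjusted p = 0.414) and stress genes (10 higher, 3 lower, 11 not passed, median 0.36, adjusted p = 0.188) did not pass. Interferon (3 higher, 4 lower, 8 not passed, median -0.10, adjusted p = 0.673) and Hox genes (3 higher, 1 lower, 4 not passed, median 0.70, adjusted p = 0.331) stayed above the threshold. So did pericyte (5 higher, 2 lower, 2 not passed, median 0.78, adjusted p = 0.0959) and haematopoietic genes (5 higher, 1 lower, 4 not passed, median 0.91, adjusted p = 0.0525). Adipocyte (3 higher, 2 lower, 1 not passed, median 1.07, adjusted p = 0.673) and Schwann cell genes (4 higher, 3 lower, 0 not passed, median 0.92, or 0.11 with members at their bound, adjusted p = 0.768) did not pass. With members at their bound the medians of the Notch, Hox, pericyte and haematopoietic lists were 0.15, 0.55, 0.61 and 0.89. In the haematopoietic list Cd74, an MHC class II chaperone, rose by 2.91 (adjusted p = 0.00019). That list passed without replicate 1 of any group (adjusted p = 0.0347 for Lgr5+ basal, 0.0468 for Lgr5- basal and 0.0404 for luminal) or without replicate 3 of the Lgr5+ (0.0273) or Lgr5- (0.0485) basal group, with pool as a replicate block (0.0422), with BeadChip as a block (0.0452) and within BeadChip 1 (0.0346). These calls use the preset correlation, and with all arrays that list had adjusted p = 0.42 with an estimated correlation. The cell cycle list passed without luminal replicate 3 (0.0443) and within BeadChip 1 (median -0.57, adjusted p = 0.015), while its median was 0.53 within BeadChip 2. With all arrays it had adjusted p = 0.79 with an estimated correlation. Of the 2 erythroid genes 0 passed, and of 4 skeletal muscle genes 2 rose, 1 fell and 1 did not pass. With BeadChip as a block 6362 genes changed and within BeadChip 1 alone 5546. Of the 5961 genes 5702 were separated, which fixes their sign within each BeadChip, and 5961 had the same sign within BeadChip 1 and 5884 within BeadChip 2. Lgr5 differed by 4.88 within BeadChip 1 (adjusted p = 3.84e-06, block 6.31e-08) and 5.51 within BeadChip 2. All 13 list calls held with BeadChip as a block and within BeadChip 1, and their medians had the same sign within BeadChip 2.

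**Figure D3:**
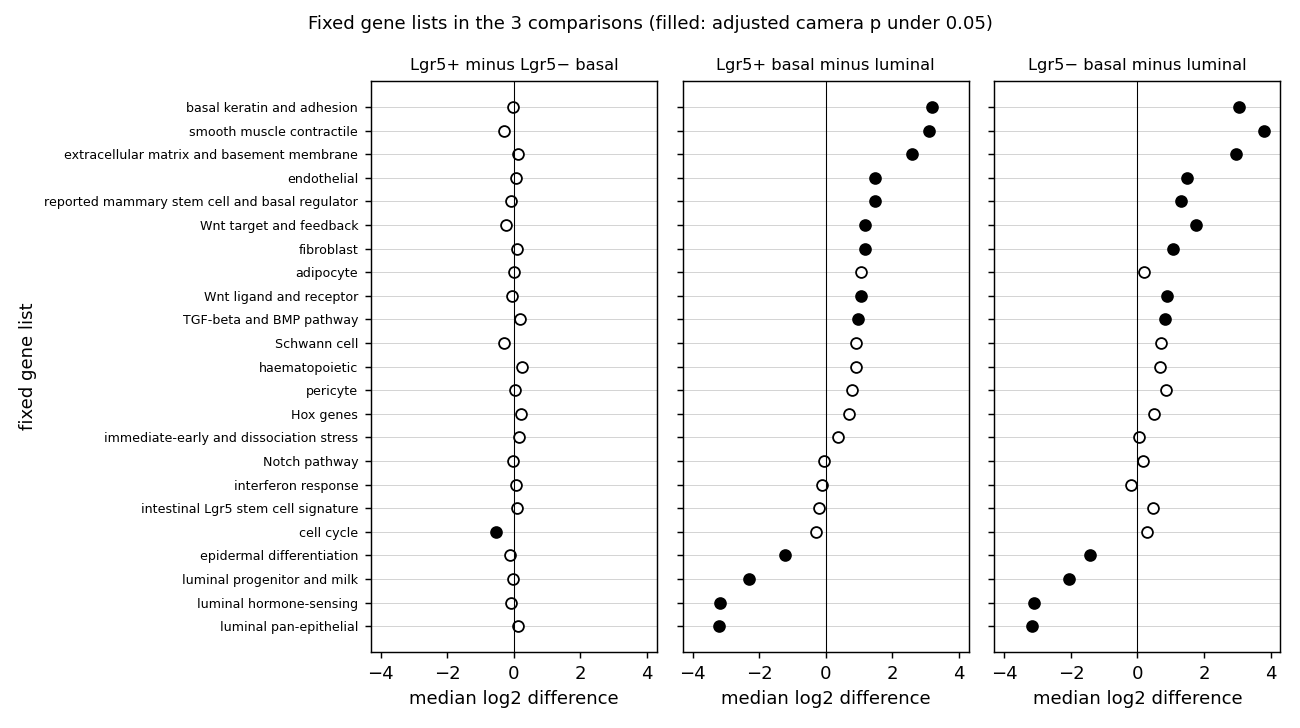
Median log2 difference (horizontal axis) of the tested members of each fixed gene list (vertical axis) in the 3 comparisons, with filled points for lists that passed in camera with a preset correlation. Basal and matrix lists lie to the right and luminal lists to the left in both comparisons with luminal cells, and the cell cycle list, at -0.55, alone is filled between the basal groups.

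Comparing Lgr5- basal with luminal cells asks the same of basal cells sorted without Lgr5. The basal programme was high here too: of 18 basal keratin and adhesion genes 16 rose and 2 did not pass, and all 17 smooth muscle genes rose. Krt5 stood at 12.09 ± 0.10 (SD, n = 3) against 5.75 ± 1.08 (log2 difference 6.33, limma adjusted p = 4.87e-07) and Myh11 at 13.47 ± 0.17 against 6.32 ± 1.49 (7.15, adjusted p = 1.95e-06). All 17 luminal pan-epithelial genes fell, Krt18 by 3.75 (adjusted p = 5.22e-08) and Krt7 by 4.64 (adjusted p = 1.88e-07). After background correction Lgr5 was at least 7.53-fold higher than in luminal cells (adjusted p = 3.04e-06), and without it the log2 difference was 1.53 (adjusted p = 0.000192). Tspan8 was lower than in luminal cells, at 8.51 ± 0.35 against 9.96 ± 0.28 (-1.44, adjusted p = 0.000346).

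In this comparison 5430 of 12148 genes changed (limma), 2668 higher and 2762 lower in Lgr5- basal cells, 3228 of them by at least 2-fold and 639 by at least 8-fold, and 55.3% were separated, against 10% by chance. The largest rises included Cxcl14 (7.19, adjusted p = 4.57e-08, at 58.6% of the array maximum), Ecrg4 (7.09, adjusted p = 4.44e-07), Myl9 (6.79, adjusted p = 2.13e-06) and Actg2, smooth muscle gamma-actin (6.77, adjusted p = 6.25e-05). They also included Igfbp3 (6.54, adjusted p = 7.04e-07), Moxd1 (6.49, adjusted p = 6.95e-06), Ism1 (6.41, adjusted p = 6.19e-06) and Id4, a helix-loop-helix regulator (6.38, adjusted p = 9.77e-07). Col14a1 was at least 71.2-fold higher (adjusted p = 2.07e-08) and Sfrp1 at least 9.93-fold (adjusted p = 1.02e-07). Among the largest falls were Rasgrf1, a Ras exchange factor (-5.56, adjusted p = 2.07e-08), Hp (-5.56, adjusted p = 1.83e-07) and Cyp3a57 (-5.55, adjusted p = 4.85e-08). Next came Muc13, a membrane mucin (-5.45, adjusted p = 3.36e-07), Cxcl15 (-5.39, adjusted p = 1.01e-07) and Dmbt1 (-5.29, adjusted p = 1.45e-05). They were followed by ABP1 (-5.15, adjusted p = 9.41e-08), Ffar4 (-5.13, adjusted p = 2.85e-07), Ly6d (-5.02, adjusted p = 4.85e-08) and the junction protein Cgn, on a probe that the authors set aside (-5.12, adjusted p = 3.08e-07). All 20 passed without any single array.

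Again 13 lists passed in camera. Fry called 16 lists, the endothelial list not among them (fry adjusted p = 0.143). Called by fry but not by camera were the intestinal signature (down, 0.0154) and, all up, pericyte (0.00234), haematopoietic (0.00638) and Schwann cell genes (0.00243). With an estimated correlation 7 of the 13 camera calls held. The 7 were basal keratin and adhesion (median 3.06, adjusted p = 5.66e-09), smooth muscle (3.81, or 3.51 with members at their bound, adjusted p = 9.44e-11), luminal pan-epithelial (-3.16, adjusted p = 1.75e-11) and hormone-sensing genes (-3.11, or -2.95 at their bound, adjusted p = 1.9e-06). To these came Wnt target (1.76, or 1.15 at their bound, adjusted p = 0.000601), TGF-beta and BMP (0.82, or 0.71 at their bound, adjusted p = 0.00075) and extracellular matrix genes (2.95, or 2.39 at their bound, adjusted p = 1.42e-11). Matrix genes had adjusted p = 0.0498 with an estimated correlation, and each of the other 6 lists had adjusted p = 0.0487 with an estimated correlation. Of 27 matrix genes 25 rose, 1 fell and 1 did not pass, with Col4a2, a basement membrane collagen, up by 6.13 (adjusted p = 8.84e-08). Of 16 hormone-sensing genes 14 fell, 1 rose (2 adjusted over the list alone) and 1 did not pass, with Prlr, the prolactin receptor, down by 4.60 (adjusted p = 2.59e-07). Of 13 Wnt targets 9 rose, 2 fell and 2 did not pass, with Wif1 up by 6.00 (adjusted p = 6.83e-08) and Nkd2 at least 13.4-fold higher (adjusted p = 1.18e-07). Of 21 TGF-beta and BMP genes 11 rose (12 adjusted over the list alone), 1 fell and 9 did not pass, with Fst up by 5.97 (adjusted p = 3.7e-08). Without luminal replicate 2, the array with more smooth muscle signal, the medians of the basal keratin and smooth muscle lists were 3.01 and 3.64, with 5181 genes changed, 4781 of them among the 5430.

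Progenitor and milk genes (3 higher, 12 lower, 3 not passed, median -2.06, or -1.72 with members at their bound, adjusted p = 0.000214) and Wnt ligands and receptors (14 higher, 5 lower, 5 not passed, median 0.88, or 0.74 at their bound, adjusted p = 0.016) were among the other 6 lists that passed. So were mammary stem cell and basal regulators (14 higher, 4 lower, 2 not passed, median 1.30, adjusted p = 0.000601) and fibroblast genes (10 higher, 1 lower, 5 not passed, 11 higher adjusted over the list alone, median 1.07, adjusted p = 0.000445). The last were endothelial genes (7 higher, 1 lower, 6 not passed, 9 and 2 adjusted over the list alone, median 1.496, adjusted p = 0.0495) and epidermal differentiation genes (2 higher, 6 lower, 2 not passed, median -1.42, or -1.13 at their bound, adjusted p = 0.0173). In that order, they had adjusted p = 0.202, 0.0729, 0.1, 0.0825, 0.742 and 0.16 with an estimated correlation. Kit fell by 4.48 (adjusted p = 4.74e-07), Snai2 rose by 6.05 (adjusted p = 1.94e-07), Dcn rose by 2.65 (adjusted p = 3.95e-07) and Flt1, a VEGF receptor, rose by 2.10 (adjusted p = 0.00253). The endothelial call was lost without Lgr5+ basal replicate 1 (adjusted p = 0.0545), Lgr5- basal replicate 1 (0.0832) or 2 (0.0554), or luminal replicate 1 (0.0667) or 3 (0.12). The intestinal signature did not pass (6 higher, 5 lower, 2 not passed, median 0.45, adjusted p = 0.836). Notch genes (4 higher, 6 lower, 4 not passed, 5 higher adjusted over the list alone, adjusted p = 0.679) did not pass either, with a median of 0.15, or -0.08 with members at their bound, a mean of 0.18 and camera down. Neither did cell cycle (3 higher, 2 lower, 19 not passed, 2 and 1 adjusted over the list alone, median 0.29, adjusted p = 0.315) and stress genes (7 higher, 4 lower, 13 not passed, median 0.04, adjusted p = 0.603). Interferon (3 higher, 4 lower, 8 not passed, median -0.20, adjusted p = 0.603) and Hox genes (3 higher, 1 lower, 4 not passed, median 0.50, or 0.27 at their bound, adjusted p = 0.619) stayed above the threshold. So did pericyte (6 higher, 2 lower, 1 not passed, median 0.87, or 0.41 at their bound, adjusted p = 0.102) and haematopoietic genes (3 higher, 1 lower, 6 not passed, 5 higher adjusted over the list alone, median 0.69, or 0.56 at their bound, adjusted p = 0.0922). Adipocyte (2 higher, 2 lower, 2 not passed, median 0.18, adjusted p = 0.836) and Schwann cell genes (4 higher, 2 lower, 1 not passed, 3 lower adjusted over the list alone, median 0.72, or 0.28 at their bound, adjusted p = 0.619) did not pass. Of the 2 erythroid genes 1 fell, and of 4 skeletal muscle genes 1 fell (2 adjusted over the list alone). With BeadChip as a block 5837 genes changed and within BeadChip 1 alone 4688. Of the 5430 genes 5346 were separated, and 5430 had the same sign within BeadChip 1 and 5428 within BeadChip 2. Lgr5 differed by 3.26 within BeadChip 1 (adjusted p = 9.72e-06, block 3.76e-07) and by 3.80 within BeadChip 2. All 13 list calls held with BeadChip as a block and within BeadChip 1, and their medians had the same sign within BeadChip 2.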

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

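Keeping the probes of the authors' flag was the only alternative chosen after the data had been seen. For named genes, settings other than the leave-outs, some of them with fewer arrays, left 6420 values with the same verdict. The same verdict meant that the call and its direction were kept, or that neither value passed, whatever the sign. Within BeadChip 2, which gives no test, it meant a shift within the spread between pools, and 117 values moved by more. Of the others, 129 lost the call, 87 gained it and 1 turned. In the fits without an array or a pool 4414 kept the verdict, 177 lost the call, 29 gained it and 0 turned. The cause of these changes was not tested. Between the basal groups, 128 genes became 52 with median centring, 36 when detection on all 9 arrays was required, 256 with pool as a random block, 331 within BeadChip 1, 1792 with array weights (weights ran from 0.31 for luminal replicate 2 to 4.37 for Lgr5+ basal replicate 2) and 11 against a 1.5-fold change. Of the 128, 49 were among the 52 and 36 among the 36, and 128 among the 1792. Against luminal cells, the test against a 1.5-fold change called 2841 (Lgr5+) and 2685 (Lgr5-) genes. Pool as a replicate block gave 160, 6475 and 5971 genes, 108 of the 160 among the 128. Without single arrays or pools the 3 counts ran from 0 to 604, 4179 to 5842 and 4007 to 5567. The 0 came without pool 1 or pool 2 (limma, with 642 and 965 genes at an unadjusted p under 0.05). Leaving out pool 3 keeps just the arrays of BeadChip 1, so it repeats that fit and its 331 genes. The verdict counts above hold this fit both among the leave-outs and among the other settings. In those fits 2 arrays per group remain. Leaving out Lgr5+ basal replicate 1, 2 or 3 gave 59, 62 or 604 genes, and Lgr5- basal replicate 1 or 2 gave 52 each. The 1 list called between the basal groups became 2 with median centring, 2 with the looser filter, 3 without a filter, 3 with array weights, 2 with the probes the authors' flag keeps, 4 with only the 6 arrays compared, and 0 with an estimated correlation or in fry (1 and 2 lists at an unadjusted p under 0.05). It ran from 1 to 4 in the leave-outs (4 without Lgr5+ basal replicate 2, luminal replicate 2 or pool 2, and 2 without Lgr5- basal replicate 2 or 3). The 13 lists against luminal cells became 0 (Lgr5+) and 7 (Lgr5-) with an estimated correlation, and ran from 11 to 15 and from 12 to 14 in the leave-outs. The rise of Lgr5 between the basal groups lost its call with median centring (1.66, adjusted p = 0.102), without a filter (1.65, 0.0565), against a 1.5-fold change (1.65, 0.402) and with only the 6 arrays compared (1.65, 0.0689), and ran from 1.37 to 1.90 in the leave-outs. It was not called without Lgr5+ basal replicate 1 (0.0509) or 2 (0.0554), Lgr5- basal replicate 1 (0.116) or 2 (0.104), pool 1 (1.70, 0.414) or pool 2 (1.63, 0.333). Without background correction the Wnt ligand (0.0529), endothelial (0.0728) and epidermal (0.0518) lists lost their calls in Lgr5+ basal against luminal cells, and the endothelial (0.105) and epidermal (0.0506) lists in Lgr5- basal against luminal cells. Against luminal cells Lgr5 differed by 5.51 within BeadChip 2 (Lgr5+), and ran from 4.80 to 5.29 (Lgr5+) and 3.19 to 3.66 (Lgr5-) in the leave-outs. Medians that turned were those of the endothelial list between the basal groups, -0.60 without Lgr5+ basal replicate 2 and -0.57 without pool 2 (leave-outs from -0.60 to 0.49), and of the Notch list in Lgr5- basal against luminal cells, -1.23 with detection required on all 9 arrays. Mcm3 in Lgr5+ basal against luminal cells was 0.002 within BeadChip 2.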

Other observations

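The tests on Lgr5 in Lgr5- cells and on single arrays were chosen after their results had been seen, while the splits of the arrays were planned.

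Among the genes that changed between the basal groups were members of 3 families that no fixed list held. The families were chosen for these genes after the values were seen, so no family was tested as a whole. Of 9 tested heparan sulfate sulfotransferases, Hs3st3a1 (-1.16), Hs3st3b1 (-1.42) and Hs6st2 (-0.96) fell in Lgr5+ cells, and the median log2 difference of the 9 genes was 0.12. Of 36 genes of cilia, Ift genes of intraflagellar transport included, 6 rose, among them Dnah1 (1.04), Nme7 (1.46), Riiad1 (1.17), Rsph9 (0.77) and Tppp3 (0.91). Their median was 0.15, and Foxj1, the regulator of motile cilia, differed by 0.86 (adjusted p = 0.0824). Of 4 genes of serine metabolism, Psat1 (-1.80) and Phgdh (-1.37) fell, Shmt1 (-0.26) and Shmt2 (-0.16) did not pass, and the median of the 4 genes was -0.81.

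Of the 10 splits of the 6 arrays of each comparison into 3 and 3, the real split alone (1 of 10) gave as many genes: 128 against at most 0 between the basal groups, 5961 against at most 0 for Lgr5+ basal and luminal cells, and 5430 against at most 0 for Lgr5- basal and luminal cells. At an unadjusted p under 0.05 in limma the real splits gave 1696, 6714 and 6279 genes and the highest others 1201, 694 and 480. In each comparison 4 splits, the real one included, part all 3 pools, and the others among them gave 0 genes. With 10 splits the share cannot fall under 0.05. Every other split mixed both populations on each side, so a difference between them widened the spread and left little room for calls. This holds above all against luminal cells, so no conclusion is drawn from the 0 counts.

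Lgr5 was detected in Lgr5- basal cells at a mean of 29.8% ± 4.8 of its background-corrected Lgr5+ signal (35.2%, 26.1% and 28.1% in pools 1, 2 and 3). Lgr5+ cells with the average levels of the Lgr5+ sort would bring all their abundant transcripts to the Lgr5- sort at that share or more. Yet of 9 other genes that rose in Lgr5+ cells with at least 500 intensity units there, 2 lay below it in all 3 pools: Tspan8 at 9.7% ± 1.3 and Sfrp1 at 13.1% ± 2.1. Cells with those average levels may therefore account for a part of the Lgr5 signal but not for its whole level. Lgr5+ cells with less Tspan8 and Sfrp1 than that average could not be excluded in this way. Background signal of the Lgr5 probe was argued against by its detection on 0 luminal arrays. Lgr5 transcripts in basal cells with little GFP stayed open and were not tested.

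Endothelial genes stood high in Lgr5+ basal replicate 2, by a median of 1.76 over the mean of the other Lgr5+ basal arrays, and other markers did to a smaller extent: haematopoietic (0.69, 7 of 10 genes above both other arrays), adipocyte (0.62, 4 of 6) and luminal pan-epithelial genes (0.44, 10 of 17), while the 2 erythroid genes were high in replicates 1 and 2 (8.50 and 8.75, against 5.34 in replicate 3). All 14 genes of the list, which drew attention to the array, lay above both other arrays. So did 20 of 23 further endothelial genes (median 1.36). These 23 were in no fixed list, and genes that passed between the basal groups had been left out. Examples were Plvap at 10.69 (8.96 and 8.20 in replicates 1 and 3) and Icam2 at 8.09 (6.58 and 5.64). More endothelial cells in that sample could give this. A shift of all genes of that level by the normalization would move random lists matched on level as far. The median of the 14 genes lay at percentile 100 of 10000 such lists, which argued against it. The percentile is no probability, since these genes drew attention to the array and move together (estimated correlation 0.829), unlike genes drawn at random. Of the 14 genes, 14 were detected on all Lgr5- basal and 12 on all luminal arrays, and 0 stand in another fixed list; gates that would remove such cells are not given in the sources used here. The 61 genes that rose in Lgr5+ cells had a median of -0.10 on the same array, and no biological explanation was tested.

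Luminal replicate 2 was the highest luminal array for 21 of 35 basal keratin, adhesion and smooth muscle genes (9 and 5 for replicates 1 and 3), which is what drew attention to it. Basal cells in that luminal sample could give this, but the excess of 21 abundant genes over the other luminal arrays was an uneven share of their basal signal. The median was 3.37% with quartiles of 1.87% and 8.68% (ratio 4.64), and 18 of the 21 shares were positive. Genes at no more than 56.8 intensity units on the other luminal arrays had shares from 0.31% (Cdh3) to 5.62% (Actg2), with 2.44% for Myh11. Itgb4 gave 25.3%, but stood at 1627.6 units there against 3739.2 in basal cells. Lamb3 (-0.29%), Tpm1 (-1.1%) and Smtn (-2.59%), at 352.7, 4504.3 and 474.1 units there, showed no excess. Acta2 gave 48.8% on the probe used and 5.31%, 6.26% and 8.99% on other probes, so shares depend on the probe. Its remaining probe (5.12%) was detected on 0 luminal arrays, so that share measures nothing. A single source should give its genes near 1 ratio. The basal signal of Krt14 (share 17.3%) and Acta2 lay near the array maximum, where it can be compressed and the share raised. Itgb4 was already high on the other luminal arrays. Uneven shares of such genes therefore cannot decide, and basal cells as the source stayed open. A shift of all genes of that level by the normalization would move lists matched on level as far. The median excess of 0.48 lay at percentile 100 of 10000 such lists, which argued against it. The percentile is no probability, since the 35 genes drew attention to the array and the matched lists hold genes drawn singly. Other lists moved on that array too, with lower luminal medians (pan-epithelial 12.17 against 12.50 and 12.49, progenitor and milk 10.36 against 11.27 and 11.01, hormone-sensing 9.44 against 9.67 and 9.98), a lower stress list (11.79 against 12.51 and 12.72) and higher Hox (5.91 against at most 5.18), endothelial (6.94 against 6.45 and 6.01), pericyte (5.63 against 5.07 and 4.92), fibroblast (6.40 against 5.83 and 5.98) and erythroid ones (8.88 against 7.68 and 7.30), and no biological explanation was tested.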
